A study of Mus musculus with 20 samples.

How the data were processed

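Chromatin immunoprecipitation with sequencing (ChIP-seq) had been carried out on F9 cells, a mouse embryonal carcinoma line that differentiates when given all-trans retinoic acid (ATRA). Per the labels' protocols, ATRA was added at 1e-06 M, the cells were fixed with paraformaldehyde, and libraries were prepared from immunoprecipitated DNA for an Illumina Genome Analyzer. Antibodies were against the retinoid X receptor RXRα, the retinoic acid receptor RARγ and RNA polymerase II (Pol II). Each was used on cells given ethanol vehicle (EtOH) for 48 h and on cells given ATRA for 2, 6, 24 or 48 h. A further RXRα ChIP came from rxra-/- cells at 48 h ATRA, and an input library held DNA without immunoprecipitation. These made 17 libraries, 1 per condition. A further 3 profiles had been combined in silico per the labels, and they were compared with their members but not used for calling.

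The deposited files listed aligned reads, 36 bp each, with chromosome, start, end and strand. Coordinates were on mm9, per the submitters' processing notes. The aligner, its settings and the handling of duplicate reads are not given in the sources used here. In 7 of the 17 files no position and strand occurred more than 1 time, and in 10 files duplicates were present, so the deposited reads had not been filtered alike. For this reason 1 read per chromosome, 5′ position and strand was kept. Chromosomes 1 to 19 and X were analysed.

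Unique reads per library ran from 3745197 to 4622480 for the 5 RXRα libraries of the course. The range was 4909794 to 5640852 for RARγ and 4209696 to 6171659 for Pol II, and the input held 3089573. Of the RXRα 48 h EtOH reads 59.2% were unique, and 1 position there held 1982 copies. Reads were moved by 0.5 of the fragment length, which the offset between strands put at 90 bp for RXRα and RARγ and 80 bp for Pol II. The input showed the same kind of offset peak, at 95 bp. Plus-strand reads alone were therefore tried, an alternative chosen after seeing the data.

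Sites were called on the 5 libraries of an antibody together. Windows of 200 bp stepped by 50 bp were compared by a Poisson test with the largest of the genome-wide rate and the scaled input rate in 1, 5 and 10 kb. Windows with p under 1e-05 and at least 3-fold over that rate were merged when within 200 bp. RXRα regions that also passed in the rxra-/- library were removed. Shared sites were RARγ sites overlapping an RXRα site by at least 1 bp, with 100 seeded placements on the same chromosome as the expectation. With input and ChIP exchanged, the rule called 31.8% as many regions as for RXRα, 43.1% for RARγ and 22.4% for Pol II. At p under 1e-09 these shares were 3.06%, 7.59% and 1.07%. For the rxra-/- library the share was 86.1%. Many of the weaker regions are therefore at the level of input noise.

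Reads in sites were compared between 2 libraries by an exact conditional binomial test, two-sided. Counts were scaled by the unique reads of each library on the analysed chromosomes. A call needed a Benjamini-Hochberg q under 0.01 and at least 2-fold. For Pol II, at least 20 reads in the 2 libraries together were needed. Ratios used for medians had 0.5 read added to both counts. With 1 library per condition such a test compares libraries, not conditions, and no difference has a replicate check. Intervals of ratios are exact Clopper-Pearson intervals at 95% and those of enrichments exact Poisson intervals at 95%. They cover counting error only. Enrichment was the read density within 150 bp of the site summit divided by that 2 to 10 kb away on both sides. This measure was added after the data were examined, because it does not depend on the scaling between libraries. Pol II ratios near receptor sites were set against 10000 seeded random lists of regions matched on mean Pol II level. Regions were drawn singly for these lists, without keeping neighbours together. Percentiles among these lists count a tie as 0.5 below, a choice made after ties at 24 h were seen.

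The caller was tested on simulated reads for chromosome 19. Of 200 planted RXRα sites of each size it recovered 9.0% at 4-fold, 41.5% at 6-fold, 88.0% at 10-fold and 100% at 20-fold, with 4 false regions among 481. Simulated background and input reads were spread evenly, which favours few false regions. This number does not carry over to the real data, where the exchange of input and ChIP gave 31.8% for RXRα. In the corresponding RARγ test 97.5% of the 10-fold sites were recovered. The binomial call was tested on counts drawn from the real site means with 200 changed sites. At 18077 RXRα sites it found 9.5% of 4-fold and 55.0% of 8-fold changes. At 15258 RARγ sites the shares were 9.5% and 67.0%, and at 39934 Pol II regions 50.5% and 88.5%. With a library-to-library CV of 20% added, 273 unchanged Pol II regions were called in the 4-fold test.

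Before the data were examined, rules were set for the regions named. They took the 8 shared sites with the largest RARγ fold over background and, of the shared sites past the rule for RARγ at 48 h, up to 4 on each side. For Pol II, regions past the rule with at least 50 reads in the higher library were ranked at each time. Up to 10 with the largest and up to 5 with the smallest ratio were named. An mm9 annotation and sequence were not used here. Gene names are therefore not given, Pol II was tested over called regions in place of genes, and gene lists, distances to gene starts, direct repeats and the Rxra locus were not analysed here. The alternatives tried were other scalings, thinning, thresholds, window sizes, duplicate handling and site sets. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are 1-based.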

Results

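The data followed RXRα, RARγ and Pol II on the genome of F9 cells during ATRA-induced differentiation. RXRα and RARγ are nuclear receptors that bind DNA as a heterodimer, and ATRA is a ligand of the RAR partner. Each antibody had 1 library at 48 h EtOH and 1 at each of 2, 6, 24 and 48 h ATRA. Only the 48 h ATRA library is thus matched in time to its EtOH control. Ratios to EtOH at 2, 6 and 24 h differ in duration as well as in treatment. The deposited RXRα libraries of the course held 4059432 to 6419730 reads, the RARγ libraries 4989751 to 5819939 and the Pol II libraries 4244928 to 6171659. The rxra-/- library held 3938912 reads and the input 3475594. There were no replicates, so each value below stands for 1 library.

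The first question was where both receptors sat. RXRα was called at 18077 sites and RARγ at 15258 sites, with a median width of 250 bp for each. Of the RARγ sites 3381, or 22.2%, overlapped an RXRα site, where random placement gave a mean of 65.3 and at most 83. Among the 500 RARγ sites with the largest fold over background the share was 52.8%. Among the 500 such RXRα sites 63.4% overlapped a RARγ site. Placement over whole chromosomes is a loose expectation. Before the filter, 1635 of 19712 RXRα regions overlapped a region of the rxra-/- library, against 36.2 by placement. The excess over placement thus does not by itself show that both receptors were bound. Receptor sites also coincided with Pol II. Of the shared sites 948, or 28.0%, overlapped a Pol II region, against 1.42% by placement. The remaining 2433 shared sites lay outside called Pol II regions. The rxra-/- filter affects this split. Before it 4272 of 19712 RXRα sites overlapped a Pol II region, and after it 3077 of 18077 did. At the stricter p under 1e-09 there were 4645 RXRα, 2768 RARγ and 1186 shared sites, so the number of sites rests on the threshold. It also rests on duplicates, since 41235 RXRα sites were called with every deposited read.

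Enrichment of both receptors at the shared sites was highest in the 2 h library. It was lowest at 48 h ATRA for RXRα, and at 24 and 48 h for RARγ. RARγ enrichment over the flanks was 5.97-fold in EtOH, 7.89 at 2 h, 6.93 at 6 h, 3.88 (95% interval 3.81 to 3.95) at 24 h and 3.83 (3.77 to 3.90) at 48 h ATRA. The same sites gave RXRα enrichments of 6.27, 9.17, 7.23, 7.36 and 5.06, and the input stood at 1.68. The 217 shared sites with a RARγ fold over 10 showed a wider range. RARγ there was 11.1-fold (95% interval 10.6 to 11.5) in EtOH, 25.1 (24.4 to 25.9) at 2 h, 16.8 at 6 h, 7.54 at 24 h and 5.44 (5.09 to 5.80) at 48 h. RXRα was 12.1 (11.5 to 12.6), 21.5 (20.8 to 22.3), 15.9, 15.6 (14.9 to 16.2) and 6.60 (6.14 to 7.07). RARγ also differed between libraries away from shared sites. At RARγ sites that were not shared the enrichments were 5.26 in EtOH, 4.22 at 2 h, 5.52 at 6 h, 3.28 at 24 h and 4.34 at 48 h, and at the 5988 Pol II regions over 10-fold they were 3.18, 2.49, 4.80, 1.74 and 3.97. RXRα differed away from shared sites as well. In the same order it was 4.61, 5.83, 5.14, 5.07 and 5.38 at RXRα sites that were not shared. At these Pol II regions it was 2.89, 3.49, 3.34, 3.85 and 4.50. How much such differences between whole libraries add to the course of either receptor at shared sites was not tested. Among 348 shared sites with at least 50 RARγ reads, 218 had their highest RARγ value at 2 h and 218 their lowest at 48 h ATRA. Of 485 such sites for RXRα, 217 were highest at 2 h, 149 at 24 h, and 322 were lowest at 48 h ATRA.

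**Figure D1:**
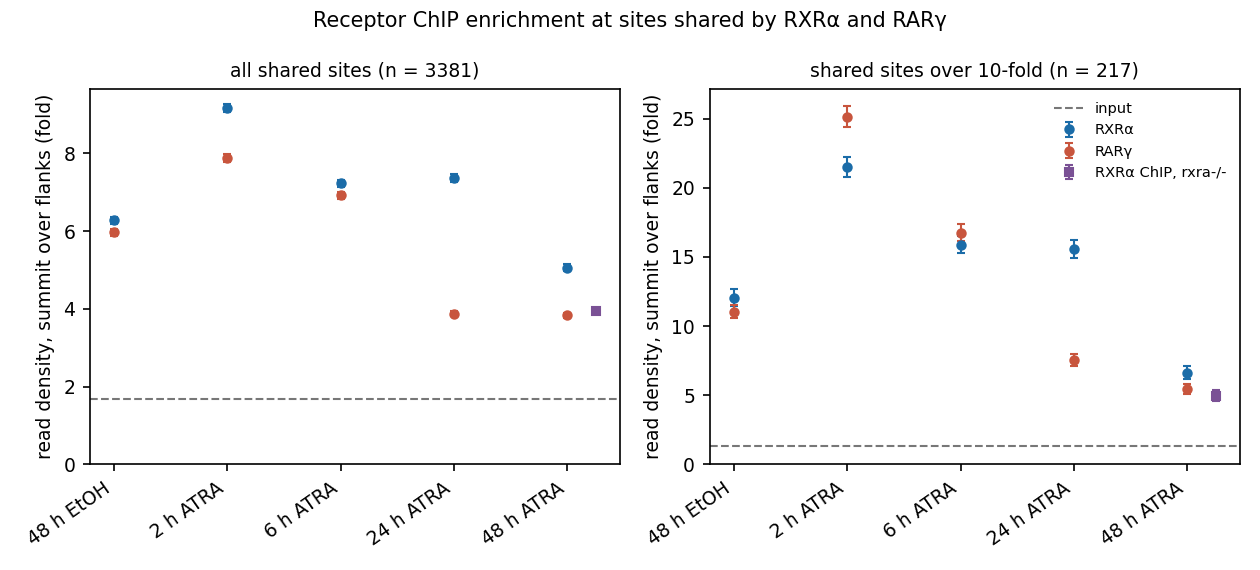
Read density at site summits over that of the flanks (fold, y axis, starting at 0) in each library (x axis) for the 3381 shared sites and the 217 of them over 10-fold. Points are single libraries, the square is the rxra-/- library, bars are 95% Poisson intervals of the summit reads, and the dashed line is the input. Shared sites were defined after RXRα regions called in the rxra-/- library had been removed, which favours a low square. RARγ peaked at 25.1 at 2 h in the stronger sites and ended at 5.44.

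The strongest shared sites followed this course in most cases. They were ranked on the same RARγ reads, all libraries combined, so a RARγ peak in 1 library is partly fixed by selection. At chr3:152396051-152396950 RARγ had 5 reads in EtOH, 286 at 2 h, 52 at 6 h, 6 at 24 h and 2 at 48 h, and the 2 h ratio to EtOH was 64.6 (27.4 to 201). RXRα reads there were 5, 100, 41, 17 and 3. At chr10:129960351-129960950 RARγ at 2 h was 15.2-fold over EtOH (8.67 to 29.1) and RXRα 5.02-fold (2.45 to 11.6). At chr10:68467901-68468400 the 2 h ratios were 8.27 (5.28 to 13.6) and 5.81 (3.52 to 10.1). By 48 h ATRA they were 0.23 (0.07 to 0.63) and 0.11 (0.01 to 0.47). The site chr13:99881801-99882400 had RARγ ratios of 4.52 (2.71 to 7.91) at 2 h and 0.11 (0.01 to 0.44) at 48 h. RARγ at chr5:23713651-23714150 was 3.32-fold over EtOH at 2 h (1.88 to 6.15), and at chr4:53802201-53802650 it was 2.66-fold (1.39 to 5.39). At the latter neither receptor had a read at 48 h ATRA. The site chr1:59014751-59015250 had a RARγ ratio of 1.18 (0.62 to 2.26) at 2 h, and at 48 h ratios of 0.24 (0.07 to 0.66) for RARγ and 0.16 (0.04 to 0.45) for RXRα. A different course was seen at chr13:46192301-46192800, where RARγ had 27, 1, 26, 5 and 15 reads in the order EtOH, 2, 6, 24 and 48 h and RXRα at most 4. At 48 h ATRA, 2 shared sites passed the rule for RARγ, and both were lower. These were chr11:106497201-106497800, with a ratio of 0.08 (0.01 to 0.30), and chr16:13474951-13475450, also 0.08 (0.01 to 0.30). Relative to the median site, 0 shared sites passed at 48 h. Whether these sites lie in genes was not analysed here.

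**Figure D2:**
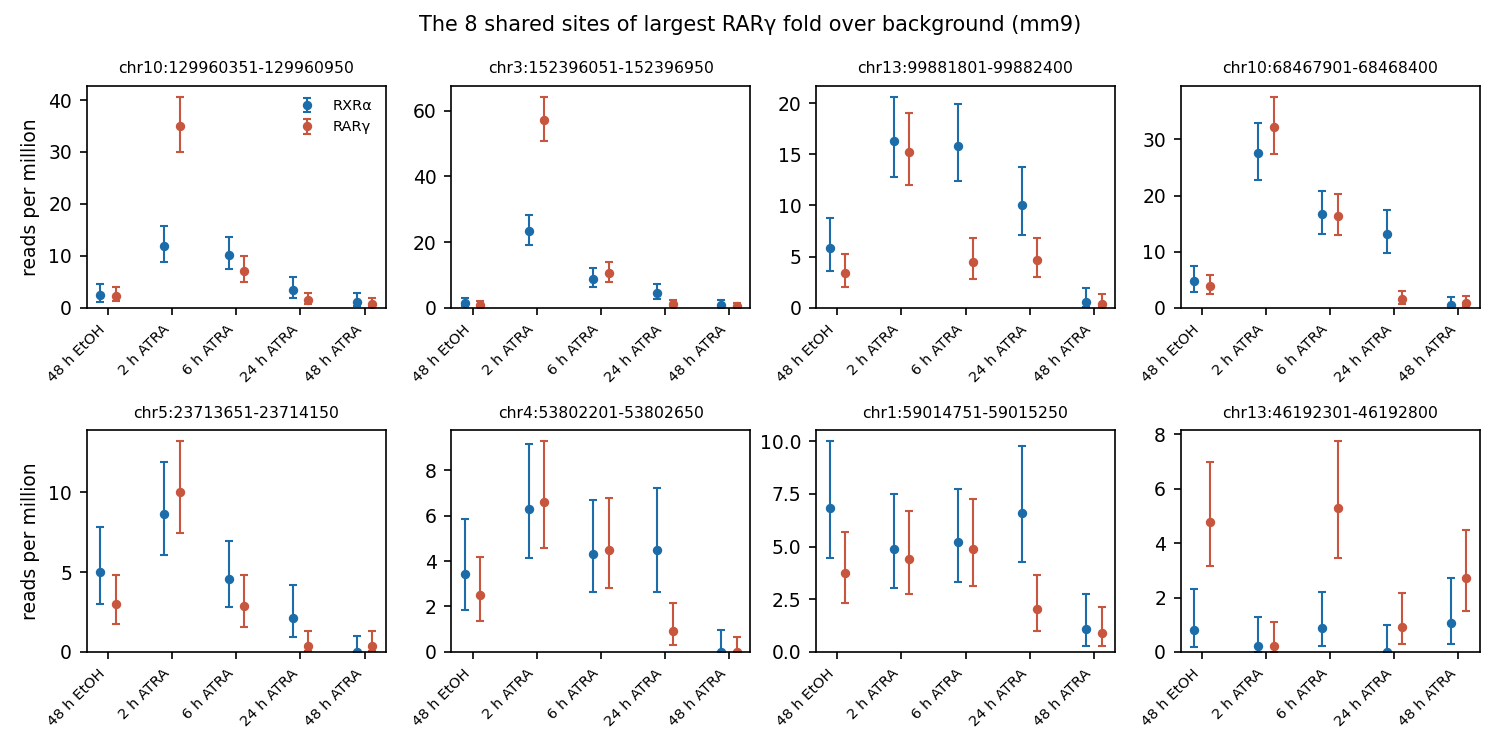
Reads scaled by all mapped reads (RPM, y axis, starting at 0) for RXRα and RARγ in each library (x axis) at the 8 shared sites with the largest RARγ fold, with 95% Poisson intervals. RARγ at chr3:152396051-152396950 went from 5 reads in EtOH to 286 at 2 h, whereas chr13:46192301-46192800 had 1 RARγ read at 2 h.

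Tested site by site, RARγ was higher than in EtOH at 155 of 15243 sites at 2 h and lower at 44, and 116 of the higher sites were shared. At 6 h there were 14 higher and 0 lower, at 24 h 11 higher and 41 lower, and at 48 h 1 higher and 3 lower. RXRα was higher at 146 and lower at 268 of 17923 sites at 2 h, and 68 and 283 at 6 h. It was higher at 105 and lower at 3 at 24 h, and 149 and 349 at 48 h. Within shared sites alone the RXRα counts were 55 higher and 17 lower at 2 h, 19 and 18 at 6 h, 45 and 3 at 24 h, and 35 and 85 at 48 h. The median log2 ratio was taken over sites with at least 10 reads in the 2 libraries together. These were 3732 to 5205 RXRα and 3828 to 5527 RARγ sites, a different set at each time. It was 0.36, -0.04, 0.14 and -0.43 for RXRα at the 4 times and -0.27, 0.20, -1.02 and -0.50 for RARγ. Relative to these medians RXRα was higher at 78, 71, 82 and 231 sites and lower at 330, 282, 6 and 228. Within shared sites the RXRα balance then turned at 2 h, to 20 higher and 23 lower, and at 48 h, to 50 higher and 44 lower. RARγ was then higher at 251, 11, 45 and 1 and lower at 28, 2, 5 and 0, so that the balance at 24 h turned from lower to higher. With an assumed CV of 20% between libraries, 10, 0, 4 and 0 RARγ calls and 82, 84, 6 and 77 RXRα calls were left at the 4 times.

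The RXRα libraries split by a property of the files, seen only after the data were examined. Reads in 1 kb bins where no RARγ, Pol II or input read fell made up 1.10% of the EtOH and 1.08% of the 24 h library, but 0.101% to 0.121% of the 2, 6 and 48 h ATRA libraries. Within the EtOH and 24 h pair, 105 sites were higher at 24 h and 3 lower. Among the other libraries, 0 sites were higher and 7 lower at 6 h than at 2 h, and 76 were higher and 337 lower at 48 h than at 2 h, of which 24 and 242 were shared. Relative to the median log2 ratio of -0.54, the balance at 48 h turned, with 151 sites higher and 110 lower than at 2 h. RARγ at 48 h had 40 sites higher and 458 lower than at 2 h, with 319 of the lower sites shared, and relative to its median of -0.39 there were 69 higher and 294 lower.

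The ratios of both receptors were compared by sign at shared sites. At 2 h, 331 of 437 shared sites with at least 20 reads for each antibody were above EtOH for both receptors, 18 were below for both and 88 differed in direction. At 6 h, 157 of 301 were above for both, 42 below for both and 102 differed. At 24 h, 59 of 173 were above for both, 51 below for both and 63 differed. At 48 h, 58 of 96 were below for both, 13 above for both and 25 differed. The same sign was thus seen at 79.9%, 66.1%, 63.6% and 74.0% of sites, where the numbers above and below for each receptor alone gave 75.4%, 56.3%, 47.0% and 60.5%, so most of the likeness at 2 h follows from both receptors being above at most sites. The minimum of reads itself depends on the change. At 276 sites with at least 50 reads in the 5 libraries of each receptor, a set chosen after seeing the data, the shares were 80.8%, 68.8%, 65.9% and 80.4%, against 77.0%, 58.2%, 48.1% and 68.0%. Across the sites compared at each time the log2 ratios of the receptors had a Spearman rho of 0.38 at 2 h, 0.43 at 6 h, 0.53 at 24 h and 0.56 at 48 h (Pearson r 0.46, 0.53, 0.68 and 0.65). Sites are not independent replicates, and no p is given.

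Fewer sites were called in single libraries. Of the 3381 shared sites, RARγ passed the rule alone at 24.9% in EtOH, 28.8% at 2 h, 28.2% at 6 h, 6.80% at 24 h and 7.93% at 48 h. RXRα passed at 21.3%, 38.0%, 29.0%, 23.5% and 10.6% of them. Over all their own sites the counts were 2755, 1685, 2690, 594 and 1219 for RARγ and 2138, 3131, 2439, 2509 and 1626 for RXRα. The RARγ total at 2 h was below that of EtOH at this threshold, but at p under 1e-09 it was above, with 696 sites against 451. A site missed in 1 library was below detection at this depth, not shown to be free of receptor.

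The rxra-/- library is an RXRα ChIP at 48 h ATRA from cells labelled rxra-/-. Over the 19712 sites called before its use as a filter, wild-type 48 h ATRA RXRα summed to 20059 RPM (reads scaled by all mapped reads) and rxra-/- to 16263, a ratio of 1.23 (1.22 to 1.25). Only 151 sites were at least 2-fold lower in rxra-/- past the rule, and 131 were higher there. These sites were called on the wild-type libraries, 2 and 48 h ATRA among them, and not on rxra-/-. That choice by itself favours ratios above 1. The answer differed between site classes. At the 15440 sites outside Pol II regions the ratio was 1.76 (1.74 to 1.79), with 88 sites lower in rxra-/- and 8 higher. At the 4272 sites overlapping Pol II it was 0.776 (0.763 to 0.789), with 57 lower and 158 higher. The q was computed within each class, so these counts do not add up to those of all sites. With the 2 h library in place of 48 h, chosen after seeing the data, 358 sites were lower and 91 higher in rxra-/-, and at the 4179 sites overlapping RARγ the ratio was 1.58 (1.56 to 1.61) against 0.790 (0.776 to 0.805) for 48 h.

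At the 217 strongest shared sites the rxra-/- enrichment was 4.95-fold (4.56 to 5.36), against 6.60 for wild type at 48 h and 21.5 at 2 h. Shared sites were defined after RXRα regions called in the rxra-/- library had been removed, so a lower value there is partly fixed by selection. Before that filter, 885 RXRα sites over 10-fold overlapped a RARγ site. Their ratio of wild type at 48 h to rxra-/- was 0.946 (0.914 to 0.979), with 41 sites lower in rxra-/- and 37 higher. The rxra-/- library was itself enriched at Pol II regions. Of its 7227 regions 73.3% overlapped a Pol II region, and at the 5988 Pol II regions over 10-fold it reached 10.7-fold, where wild-type RXRα libraries had 2.89 to 4.50 and the input 3.20. The library therefore differed from the wild type in more than signal at receptor sites. The genotype label was not checked at the DNA level, since the Rxra locus was not analysed here.

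**Figure D3:**
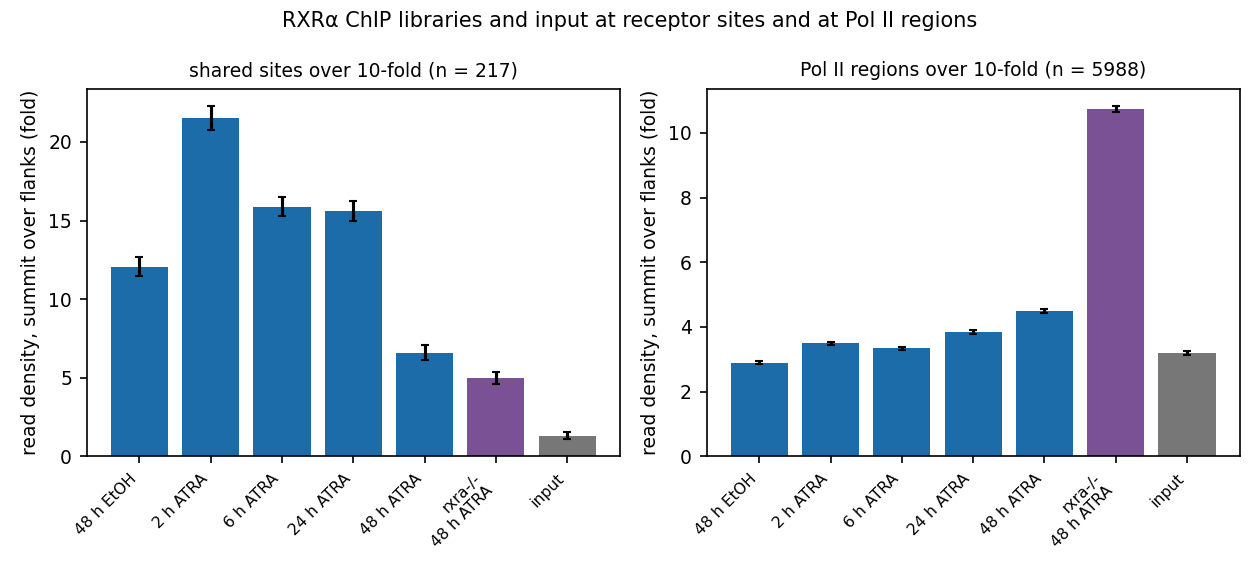
Read density at summits over that of the flanks (fold, y axis, starting at 0) for the RXRα ChIP libraries and the input (x axis) at 217 shared sites and at 5988 Pol II regions, both over 10-fold; bars are single libraries with 95% Poisson intervals. The rxra-/- library was 4.95-fold at the shared sites and 10.7-fold at Pol II regions. Shared sites were defined after RXRα regions called in the rxra-/- library had been removed, which favours a low value there.

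Pol II was called at 39934 regions. These held 10.8% of the reads in EtOH, 19.4% at 2 h, 21.6% at 6 h, 11.4% at 24 h and 22.6% at 48 h ATRA, against 3.84% of the input. Scaled by the unique reads on the analysed chromosomes, 5412 regions were higher than in EtOH at 2 h and 18 lower. There were 5508 and 12 at 6 h, 89 and 63 at 24 h, and 8232 and 25 at 48 h. With an assumed CV of 20% between libraries 416, 377, 0 and 2154 of either direction were left. The median region itself was shifted by a log2 ratio of 0.91 at 2 h, 0.98 at 6 h, 0.12 at 24 h and 1.14 at 48 h. Relative to that median 365 regions were higher and 307 lower at 2 h, 166 and 69 at 6 h, 62 and 116 at 24 h, and 451 and 432 at 48 h. Between the libraries of like share, 797 regions were higher and 821 lower at 6 h than at 2 h, 684 were higher and 253 lower at 48 h than at 2 h, and 1624 were higher and 742 lower at 48 h than at 6 h. Relative to the medians there were 660 and 949, 221 and 520, and 1024 and 1071 for these pairs, so that the balance of both pairs with 48 h turned. Whether Pol II rose at all regions or the 2, 6 and 48 h libraries were more enriched was not separable with 1 library each. The RXRα libraries split between the same times, with EtOH and 24 h apart from 2, 6 and 48 h ATRA. Whether both splits have a common source, such as a batch, was not tested.

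Some regions stood far above that shift at 1 or more times. Of 34 regions named as higher, 9 lay within 10 kb of a shared site and 25 farther away. Of the 31019 Pol II regions in the comparison with matched lists below, 9.23% lay within 10 kb. The 34 were the largest ratios pooled over the ATRA times, some of them neighbours, and do not stand for all higher regions. Among regions within 10 kb, 19.73%, 22.04%, 0.5938% and 20.29% passed the rule as higher at 2, 6, 24 and 48 h. Among all 31019 the shares were 17.45%, 17.76%, 0.2869% and 26.54%, so at 48 h the share near shared sites was the lower. At chr19:37772201-37772650, 1600 bp from a shared site, Pol II had 1 read in EtOH, 10 at 2 h, 53 at 6 h, 92 at 24 h and 119 at 48 h. The ratios to EtOH were 47.7 (8.20 to 1919) at 6 h and 101 (17.8 to 4028) at 48 h, or 4.03 and 4.94 on the log2 scale above the median region. The neighbouring chr19:37776451-37777300 had 6, 4, 25, 60 and 93 reads. Pol II at chr6:52141851-52142400, 2250 bp from a shared site, was 11.2-fold over EtOH at 6 h (4.13 to 42.9) and 7.62-fold at 24 h (2.67 to 29.9). At chr6:52108201-52109750, 4550 bp from a shared site, the ratio of 1.95 (1.25 to 3.10) at 2 h was 0.04 above the median region on the log2 scale and did not pass the rule. The later ratios were 4.78 (3.20 to 7.37) at 6 h, 4.65 (3.09 to 7.24) at 24 h and 5.86 (3.96 to 8.98) at 48 h. The region chr11:96439101-96440750 overlapped a shared site and was 7.92-fold (2.48 to 40.4) at 2 h, 30.6-fold (10.2 to 151) at 6 h, 14.2-fold at 24 h and 7.37-fold at 48 h. Relative to the median region its log2 ratio was highest at 6 h, at 3.74. At chr18:61194351-61196400, 13400 bp from a shared site, Pol II was 8.56-fold over EtOH at 2 h, 11.4-fold at 6 h, 6.53-fold at 24 h and 11.9-fold at 48 h, and at chr4:41044851-41045450, 2600 bp from a shared site, 14.5-fold at 2 h, 12.8-fold at 6 h, 4.35-fold (1.59 to 14.8) at 24 h, where it did not pass the rule, and 16.1-fold at 48 h.

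The next 3 high regions lay 71650 bp or more from a shared site. At chr6:135015501-135015900 there were 0 reads in EtOH and 67 at 2 h, at least 16.6-fold against a floor of 3 reads in EtOH, with an exact lower limit of 13.1. At chr8:12395451-12395850 the 48 h ratio was 65.4 (11.4 to 2618), and at chr1:137584501-137584850 it was 50.1 (8.66 to 2014). Among the lower regions, chr14:51415051-51416250 had ratios of 0.43 (0.30 to 0.62) at 2 h, 0.52 at 6 h, 0.29 at 24 h and 0.30 (0.19 to 0.47) at 48 h, and passed the rule at 2, 24 and 48 h. Pol II at chr7:152127051-152129450 was 0.25 (0.16 to 0.37) at 24 h and 0.41 (0.30 to 0.55) at 48 h. At chr3:52912351-52917350 it was 0.37 (0.27 to 0.50) at 48 h but 1.83 (1.49 to 2.25) at 6 h. The region chr13:31774301-31775850 overlapped a shared site and was 0.36 (0.21 to 0.60) at 48 h. The lower regions chr16:57391601-57391800 and chr6:3151401-3151650 held 57 and 48 input reads within at most 250 bp, and their 24 h ratios were above 2.

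The last question was whether Pol II near receptor sites moved apart from the rest. The 2863 tested Pol II regions within 10 kb of a shared site had a median log2 ratio of 0.93 at 2 h and 1.04 at 6 h. Matched random lists had 0.81 and 0.88, and the observed medians lay above all 10000 of them. At 24 h both medians were 0.12. At 48 h the regions near shared sites, at 0.86, lay below all 10000 lists, whose median was 0.95. The lists that follow were chosen after seeing the data. The 135 regions near shared sites over 10-fold had medians of 0.97, 1.11, 0.26 and 0.73, against 0.79, 0.84, 0.12 and 0.90. The 182 regions near the 116 shared sites where RARγ was higher at 2 h had medians of 1.39 at 2 h, 1.43 at 6 h, 0.18 at 24 h and 1.21 at 48 h, and matched lists 0.83, 0.89, 0.12 and 0.99. Without regions that overlapped a shared site, 144 regions were left, and their medians at 2 and 6 h, 1.29 and 1.15, still lay above all random lists. These percentiles describe the libraries, and all 4 times share the EtOH library. Regions near 1 site can move together, which the singly drawn lists do not copy. The range of the lists can thus be too narrow, and a place beyond all 10000 can overstate a difference.

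**Figure D4:**
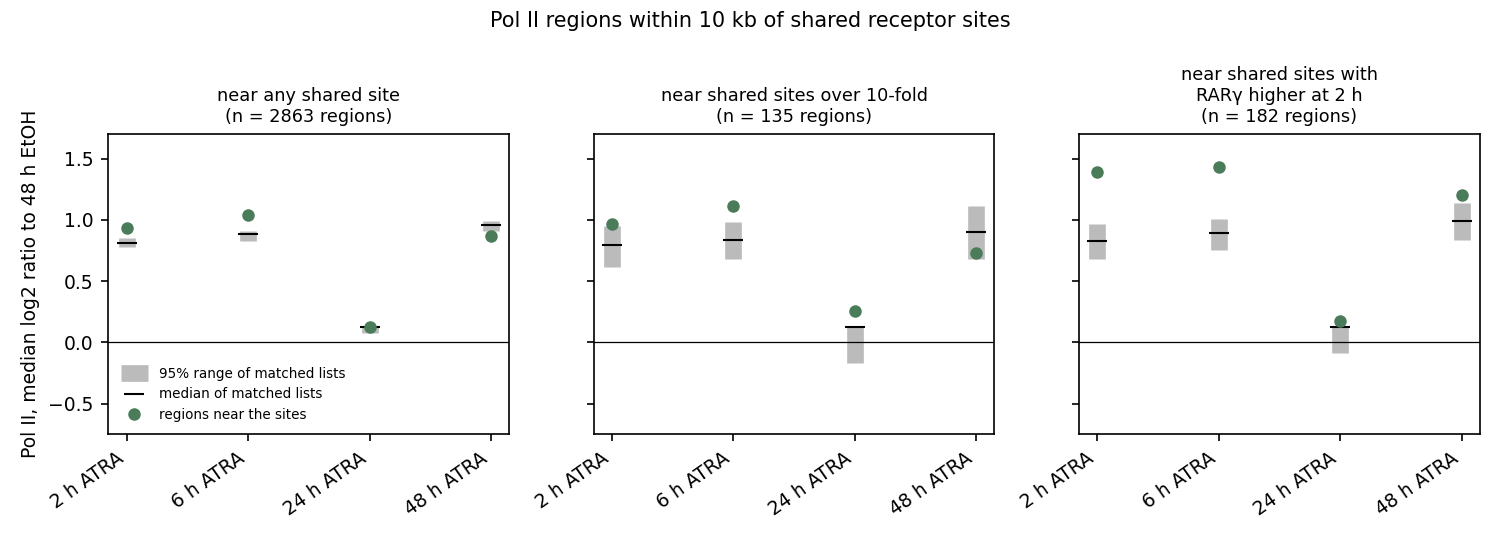
Median log2 ratio of Pol II to 48 h EtOH (y axis) at each ATRA time (x axis) for regions within 10 kb of shared sites (points), with the median (dash) and 95% range (grey) of 10000 random lists matched on Pol II level. The 182 regions near sites with RARγ higher at 2 h stood at 1.39 at 2 h, against 0.83 for matched lists.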

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

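The tests of a difference between receptors and the check of the combined profiles were chosen after the data were seen. Shared sites with at least 20 reads for each antibody were tested for a difference between the RXRα and RARγ ratios to EtOH, with a normal test of the difference of log ratios and q under 0.01. At 2 h, 2 of 437 sites differed, at 6 h 2 of 301 and at 24 h 2 of 173. At 48 h 0 of 96 did. At 2 h these were chr18:38735651-38736100, where RARγ was 8.91-fold over EtOH (4.44 to 20.3) and RXRα 1.10-fold (0.59 to 2.05), and chr14:99506901-99507250, with 6.21 (3.14 to 13.7) and 1.08 (0.72 to 1.64). At 6 h chr4:64158751-64159100 had RXRα at 0.10 (0.04 to 0.21) and RARγ at 1.53 (0.68 to 3.55), and chr6:99473351-99473750 had 0.46 and 5.75 (2.35 to 16.9). At 24 h RXRα was the higher at chr2:165856551-165857000, with 13.7 (4.38 to 69.3) against 0.49 (0.20 to 1.15), and at chr10:68467901-68468400, with 2.79 (1.60 to 5.08) against 0.38 (0.15 to 0.88). The RXRα reads at chr4:64158751-64159100 were 66 in EtOH and 86 at 24 h against 7 to 13 in the other RXRα libraries of the course, the split between files described for RXRα. Each comparison sets 4 libraries against each other and has no replicate check.

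The combined Pol II profile, which no comparison used, did not equal its members. The combined RXRα and RARγ profiles each held exactly the reads of their 5 members. The Pol II ATRA profile held 20902064 reads, and its 4 libraries 20898472. All positions of the 2 and 6 h libraries were present, and 98.0% of the 6 h positions occurred in more copies than in the 6 h library, against 0.644% of the 24 h positions. Of the 24 h positions 65.2% were present and of the 48 h positions 37.2%. On chromosome 10 the shares were 100% and 4.66%, and on chromosome 5 they were 2.91% and 100%. How that file was put together is not given in the sources used here.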

How the results depend on the processing

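Plus-strand reads, shared sites alone, the set of 276 sites, merged Pol II regions, calls on part of the libraries, the 2 h library against rxra-/-, and the Pol II lists near strong sites, near sites with RARγ higher at 2 h or without overlap were chosen after seeing the data. No paired analysis was possible because each group holds 1 library. For the same reason no library could be left out of a group. Not run for want of an mm9 annotation or sequence were Pol II over promoters or whole genes, gene lists, shares of sites near gene starts, direct repeats and the Rxra locus. Where the cause of a change is not plain from the setting, the cause was not tested.

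Every deposited read gave 41235 RXRα sites, and 4342 occupied in EtOH, whose file has the most duplicates. At p under 1e-09 there were 4645 RXRα, 2768 RARγ and 1186 shared sites. In the order EtOH, 2, 6, 24 and 48 h, 683, 1059, 558, 1039 and 377 RXRα sites and 451, 696, 671, 89 and 125 RARγ sites were then occupied. Without input, 24233 RARγ sites were called. RXRα without the EtOH and 24 h libraries gave 11655 sites. RARγ from the 2 and 24 h libraries gave 3454 sites, 1234 of them shared. Plus-strand reads alone gave 6146 RXRα, 4401 RARγ and 1302 shared sites. The counts of RXRα and RARγ sites with 400 bp windows, or from the union of single libraries, and the shared count at 50% reciprocal overlap were within 1.5 times the reported ones. In all, 123 values under other settings stayed within that limit or, for the matched lists, kept their direction and side. Beyond it moved 71, while 2 reversed, 2 newly passed the lists and 1 no longer did. Calls against EtOH were judged on higher and lower together, so a turned balance does not count as reversed. RARγ at 24 h stayed within the limit, though relative to the median it went from 11 higher and 41 lower to 45 and 5. All 24 for the 8 named shared sites stayed within the interval of the reported ratio, though plus-strand reads moved the RARγ ratio at 2 h by over 1.5 times to 25.1 at chr10:129960351-129960950, 1.84 at chr1:59014751-59015250 and 0.0753 at chr13:46192301-46192800.

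In the knockout comparison, sites called on the 48 h ATRA library alone gave 259 lower in rxra-/- and 13 higher. That set was chosen on the library it favours. Sites overlapping RARγ gave 51 lower and 115 higher, sites outside Pol II regions 88 lower, and the 2 h library 358 lower.

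Calls against EtOH are given as higher and lower together, in the order 2, 6, 24 and 48 h. For RXRα they were 72, 37, 48 and 120 in shared sites alone, 82, 84, 6 and 77 with an assumed CV of 20%, 761, 585, 305 and 946 with every deposited read, and 148, 152, 18 and 158 with plus-strand reads. With every deposited read the RXRα balance at 2 h turned to 384 higher and 377 lower, and in shared sites it turned at 2 and 6 h. For RARγ shared sites alone gave 120 at 2 h, 12 at 24 h and 2 at 48 h, the CV gave 10, 0, 4 and 0, and plus-strand reads gave 44, 3, 7 and 0. Thinning gave 29 RARγ calls at 24 h and 1 at 48 h, the median ratio 1 at 48 h, and every deposited read 11 at 48 h. In shared sites the 24 h balance turned to 8 higher and 4 lower. For Pol II the median ratio gave 672 at 2 h, 235 at 6 h and 883 at 48 h. Quantile normalization with no test gave 2470 at 6 h, 1800 at 24 h and 4154 at 48 h. The CV left 416, 377, 0 and 2154, and plus-strand reads 2317, 2681, 43 and 4790, with the 24 h balance turned to 17 higher and 26 lower. Under the CV, 415 of the 416 Pol II calls at 2 h were higher, since the shift of the median stayed.

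For Pol II near shared sites, the median log2 difference from matched lists at 2 and 6 h stayed above 0, with at least 9807 of 10000 lists below, for distances of 5 or 50 kb, any RXRα or RARγ site, and each list chosen after seeing the data. At 24 h it was 0.13 near sites over 10-fold and 0.0553 near sites with RARγ higher at 2 h, past the lists in both. At 48 h it was -0.18 near sites over 10-fold, within the range of the lists. It turned to 0.22 near sites with RARγ higher at 2 h, and to 0.19 there without overlap. Depth limits the calls at single sites, since 9.5% of planted 4-fold changes were found for either receptor.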

Other observations

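The 449 RXRα sites over 10-fold without a called RARγ site held 3945 reads at their summits in EtOH, 4747 at 2 h, 4036 at 6 h, 4300 at 24 h and 3237 at 48 h. Their enrichments of 6.01, 18.8, 15.1, 6.74 and 15.4 differed more because the flanks held 34981 reads in EtOH and 34018 at 24 h, against 11222 to 14223 in the other RXRα libraries of the course. A further 203 RARγ sites over 10-fold overlapped no RXRα site kept after the rxra-/- filter. RARγ there was at 13.5 in EtOH, 16.5 at 6 h, 5.42 at 24 h and 8.55 at 48 h. At 2 h its 95% interval was 11.5 to 12.5. RXRα was enriched there too, at 7.20 to 13.6, and rxra-/- stood at 9.64. RXRα regions overlapping a RARγ site numbered 4179 before the filter and 3372 after it. The 203 can therefore include sites whose RXRα region was called and then removed, which favours high RXRα and rxra-/- values. Pol II at chr12:110778801-110779500 had 1, 72, 3, 0 and 90 reads in the order EtOH, 2, 6, 24 and 48 h. At chrX:70284251-70285250 it had 2, 72, 0, 2 and 73, and at chr15:79801151-79801750 it had 5, 137, 12, 5 and 137. The rxra-/- library held 23, 19 and 27 reads at these 3 regions and the wild-type RXRα library at 48 h 0, 1 and 1.

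Of the tests that follow, all were chosen after the results were seen except that of the excess over Pol II quartiles, which was fixed before its own result but after the likeness to Pol II was known. The number of comparison libraries in the tests of read density was corrected to 11 after their results were seen, with the bounds kept. For the first pattern, 862 RXRα sites had at least 4-fold more reads in the EtOH and 24 h libraries together than in the 2, 6 and 48 h libraries, with q under 0.01. At 641 sites chosen alike on EtOH without the 24 h library, the median ratio of 24 h to EtOH was 0.864 (quartiles 0.581 and 1.12), which argues against binding that ATRA removes and keeps away at 24 h for the set, though 123 sites lay under 0.5. The 11 RARγ, Pol II and input libraries had a median density of 0.178 of the genome average at the 862 sites, and 376 sites had no read in any of them. For such sites alignments to repeated sequence kept in these 2 files alone are a candidate explanation. It does not cover the 307 sites at 0.5 or more of the average or more, among them the longest, chr8:19750001-19764250, which lay above it.

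In the second pattern 150 RXRα sites had the opposite bias, and 13 of them overlapped a RARγ site. At chr1:57029501-57030550, an example chosen after its values were seen, RXRα had 9, 258, 241, 11 and 243 reads, RARγ at most 19 and rxra-/- 16. Repeated sequence is argued against by a median density of 4.56 times the genome average in the 11 other libraries. Binding that ATRA starts and keeps stays open: at 98 sites chosen without the 24 h library, the median ratio of 24 h to EtOH was 1.41 (quartiles 1.00 and 5.02), and 40 were over 2, though choosing sites on low EtOH counts raises this ratio by itself. It cannot be told apart from a batch of these 3 libraries, since there was 1 library per condition. The Pol II libraries at the same times were those with the larger share of reads in Pol II regions.

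In the third pattern, the enrichment of the rxra-/- library at Pol II regions, transcribed chromatin common to all libraries is argued against as the whole cause, since the highest wild-type RXRα or input enrichment was 0.419 of the rxra-/- value. The excess of rxra-/- over wild-type RXRα at 48 h, as a fraction of the excess of Pol II over the same library, was 0.234, 0.264, 0.244 and 0.212 from the weakest to the strongest quartile of Pol II regions outside RXRα sites. The highest was 1.25 times the lowest, where a limit of 2 had been set. Material of a Pol II ChIP in the rxra-/- library would give such a fraction, as a hypothesis. Any other enrichment of this library alone in proportion to Pol II would give it too, so the test does not decide between them. Loss of RXRα itself stays open and untested, since there was 1 rxra-/- library.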
